A study of Homo sapiens with 15 samples.

How the data were processed

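RNA was sequenced from 15 cultures of HepG2, a human hepatoma cell line often used as a hepatocyte model. The labels give 5 groups of 3 biological replicates each. NC was the blank control, and FFA received 500 µM free fatty acids. FCL, FCM and FCH received the same fatty acids with cyanidin-3-rutinoside (C3R), an anthocyanin pigment of fruit, at 25, 50 and 100 µM. The labels do not say how far apart the replicates were cultured, so p-values measure the spread between these cultures. Per the labels' protocols, messenger RNA was selected on oligo(dT) beads, and libraries were made with a stranded Illumina kit. The labels number the libraries 1 to 15 in the order of the groups.

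The deposited values are TPM, a length-normalized share of transcripts, for each of 63241 Ensembl genes, with a gene symbol where the table gives one. Per the labels, the authors aligned the reads to an Ensembl human genome with HiSat2 and estimated expression with RSEM. The tool versions, the annotation release and the use of strand in counting are not given in the sources used here. For that reason no coordinates are printed, and genes that overlap another gene or have near-identical copies are uncertain. TPM carry no sequencing depth, so the depth of each library is unknown and no counting interval can be given.

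The values themselves showed a further step that no label mentions. In 12775 genes, the 14 libraries other than FCH replicate 3 shared 1 offset per gene from whole multiples of 0.01 TPM, while the other 50466 genes were whole multiples in these libraries. The 14 columns summed to between 1001311 and 1001313 TPM and that of FCH replicate 3 to 990018 TPM. A mean-only empirical Bayes batch adjustment with FCH replicate 3 as a batch of its own and the groups kept was recovered from these offsets. Re-applied to the recovered values, it returned all 191625 deposited values of these genes to within 4.84e-06 TPM. Under this model FCH replicate 3 kept 41.6% of its deviation from the mean of the other 2 FCH libraries. The other 14 libraries moved by a median of 0.188% of a gene's mean and by 2.99% at most. Over the 12275 adjusted genes that reached 1 TPM in at least 3 libraries, on the log2(TPM + 1) scale, the mean correlation of FCH replicate 3 with FCH replicates 1 and 2 was 0.996 as deposited and 0.989 with the adjustment undone. Over all 12950 tested genes, those not adjusted included, its correlations with these 2 as deposited were 0.986 and 0.987. The adjustment can therefore make the spread within FCH too small. The deposited values were used throughout, and the values with the adjustment undone served as an alternative.

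Genes with a TPM of at least 1 in at least 3 of the 15 libraries were tested, 12950 in all. Values were taken as log2(TPM + 1), a scale that understates the change of genes with low TPM. All 15 libraries entered 1 linear model with a mean per group and no covariate (limma 3.58.1 in R 4.3.3, empirical Bayes with a mean-variance trend). Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested in each comparison, and a gene was called at an adjusted p under 0.05 with no minimum fold change. Adjusted p-values of genes below come from this model, except where the dose trend or an alternative is named. The C3R dose trend was a slope on the dose in the 12 libraries given fatty acids, stated per 100 µM.

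A total of 40 gene lists were fixed before the data were examined, and 36 had the 5 tested members needed for a test. Lists were tested with camera, which compares the members with all other genes, at a preset correlation of 0.01 between genes and again with an estimated correlation. The 4 lists not tested were those for CAR and PXR metabolism, metallothioneins, endothelial markers and leukocyte markers. Covariances between the fatty acid change and the C3R change were compared with 100 simulated draws in which nothing changed and the FFA libraries were shared in the same way.

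The genes named in the text followed a rule fixed before the data were examined. For FFA against NC and for each C3R group against FFA, it took the 5 largest rises and the 5 largest falls among called genes with a symbol whose groups did not overlap. It added up to 4 called members per list with the smallest p-values, and a panel of 20 lipid genes, of which 16 were tested. Genes outside the rule are stated as such. The design, its comparisons and most alternatives were likewise chosen before the data were examined.

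Alternatives were a pseudocount of 0.1, no filter, a minimum mean of 5 TPM, median-of-ratios rescaling, quantile normalization and leaving out the mitochondrial genome's genes. Others were array weights, a replicate block, a fit on the compared groups alone, a minimum log2 change of 1, cross-fitting, the dose as a rank, the dose trend without FFA and leaving out each library. Chosen after seeing the data were undoing the batch adjustment, alone and with array weights, removing each library's trend over GC content and length, a term for the libraries numbered 12 to 15, and leaving FCM replicate 3 out of the covariance of the C3R groups. GC content and length came from GENCODE release 29, which covered 96.2% of the tested genes. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

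The steps were tested on simulated data. With 200 of the 12950 genes changed, the comparison of FFA with NC recovered 11.9% of those changed by 0.5 on the log2 scale, 74.6% at 1 and 95.5% at 2, with 12 false calls among 133. For FCH against FFA these shares were 7.5%, 58.2% and 93.9%, with 4 false calls among 110. For FCM against FFA they were 9%, 62.7% and 93.9%, with 4 among 114, and for FCL against FFA 6%, 77.6% and 93.9%, with 5 among 123. All 3 lists raised in a simulated FFA against NC comparison were called. So was 1 list that was not raised but shared genes with a raised list, and 0 lists without shared genes. Some of the fixed lists share members, so lists called together are not all separate results. A planted slope of -0.3 between the fatty acid and the C3R change was estimated at -0.296.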

Results

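Gene expression was measured by RNA sequencing in 15 HepG2 cultures. There were 3 blank controls (NC), 3 cultures given 500 µM free fatty acids (FFA) and 3 cultures each given the fatty acids with 25, 50 or 100 µM C3R (FCL, FCM and FCH). Between 11268 and 12293 genes reached 1 TPM in a library. The 50 most abundant genes held between 28.6% and 36.2% of the TPM, and the genes of the mitochondrial genome between 6.03% and 12%. Within groups, correlations of libraries across the 12950 tested genes, on the log2(TPM + 1) scale, lay between 0.966 (FCM replicates 2 and 3) and 0.987 (FCH replicates 1 and 3). FFA replicates 2 and 3, all 3 FCL replicates and FCM replicate 3 each correlated better with a library of another group than with any of their own, and FCM replicate 1 did so equally well at 0.986. TPM do not give sequencing depth, so the depth of each library is unknown. The deposited values of FCH replicate 3 carried a batch adjustment. The first principal component, 22.7% of the variance, set FCM replicate 3 (score 47.9) apart from FCM replicates 1 and 2 (-0.2 and -2.2).

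The comparison of FFA with NC asks what the fatty acids alone changed. Of the tested PPAR targets 11 of 20 rose, of cholesterol synthesis and uptake genes 16 of 25 and of NRF2 targets 16 of 27, and all 4 tested metallothioneins fell. With an estimated correlation the adjusted p of the first 3 lists was 0.0948, 0.0948 and 0.0404. FABP3, a cytosolic fatty acid binding protein, rose from 2.62 ± 0.653 TPM to 102 ± 17.8 TPM (SD, n = 3 each), a log2 change of 4.83 (SE 0.31, adjusted p = 5.82e-07 by limma). PDK4, a kinase that restrains glucose oxidation, rose by 3.28, and ANGPTL4, a secreted inhibitor of lipoprotein lipase, by 2.99, from 94.9 ± 12.9 to 762 ± 104 TPM. The hormone gene FGF21 rose by 2.73 and PLIN4, which coats lipid droplets, by 2.47. In all, 955 of 12950 genes were called, 708 higher and 247 lower in FFA. Of these, 258 changed by at least 1 on the log2 scale.

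Among the lists of lipid genes, cholesterol synthesis and uptake had 16 of 25 tested members higher and none lower, or 21 adjusted over the list alone (median log2 change 0.78, camera adjusted p = 5.11e-16). The adjusted p was 0.0948 with an estimated correlation. INSIG1, which retains the sterol sensor complex in the endoplasmic reticulum, rose by 2.12, SQLE by 1.61, ACAT2 by 1.05 and FDPS by 0.98. Of the 20 tested PPAR target genes 11 rose, or 13 adjusted over the list alone (median 0.82, camera adjusted p = 2.5e-11, and 0.0948 with an estimated correlation). They included PDK4, ANGPTL4, FGF21 and PLIN2, the last from 0.345 ± 0.135 to only 1.87 ± 0.5 TPM.

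Fatty acid oxidation and ketogenesis had 7 of 27 members higher, or 8 adjusted over the list alone, with HADHB at 1.22, ETFA at 0.95, ACADVL at 0.71 and ECH1 at 0.71. CPT1A, the gate of mitochondrial fatty acid import, rose by 1.03 (SE 0.15). Lipid droplet genes rose in 5 of 19 (6 over the list alone), including LIPE at 1.47 and AGPAT2 at 0.82. Fatty acid uptake and activation rose in 4 of 12 (5 over the list alone, where 1 also fell), including ACSL5 at 1.40 and FABP1 at 1.23. Lipogenesis and desaturation rose in 5 of 17, also over the list alone, including the desaturases SCD (0.94) and FADS1 (0.86). FASN (-0.33), SREBF1 (-0.46) and ACACA (0) did not pass the test. Camera adjusted p-values of these 4 lists were 0.00331, 0.000489, 0.0236 and 0.0236, and with an estimated correlation the adjusted p-values were 0.429, 0.37, 0.405 and 0.515.

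NRF2 target genes, which serve detoxification and redox balance, rose in 16 of 27, or 19 adjusted over the list alone (median 0.72, camera adjusted p = 5.11e-16). This was the 1 list of 36 that also passed with an estimated correlation, at adjusted p = 0.0404. AKR1C1 rose by 3.34 (SE 0.23), AKR1C2 by 3.09, AKR1C3 by 2.15, and the ferritin chain FTH1 by 1.65 to 23370 ± 3610 TPM. The AKR1C genes are close paralogs, so the division of reads among them is uncertain. AHR target genes rose in 5 of 8, or 8 over the list alone, with CYP1A1 at 1.73 (camera adjusted p = 7.66e-07, and 0.0948 with an estimated correlation). In the ATF4 and integrated stress response list 11 of 28 rose and 1 fell, or 13 and 2 over the list alone. ATF3 rose by 2.11 and PPP1R15A by 1.49, while DDIT4, an inhibitor of mTORC1 signalling, fell from 637 ± 38.3 to 309.8 ± 49.1 TPM (-1.05, SE 0.13). The camera adjusted p of that list was 8.02e-05, and 0.323 with an estimated correlation.

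Autophagy and lysosome genes rose in 9 of 25, or 13 over the list alone. The autophagy receptor SQSTM1 rose by 1.93, the protease gene CTSD by 1.42 and CTSL by 1.03 (camera adjusted p = 5.65e-09, and 0.203 with an estimated correlation). Immediate early genes rose in 9 of 18, or 11 over the list alone, including JUND (1.44) and KLF6 (1.24), with a camera adjusted p of 5.65e-09 and an adjusted p of 0.194 with an estimated correlation. Of TGF-beta and matrix genes 6 of 16 rose, or 10 over the list alone, including SMAD7 (1.31) and VIM (0.81), with adjusted p-values of 1.03e-05 and, with an estimated correlation, 0.334. The lists of NF-kB, p53, hypoxia, endoplasmic reticulum chaperone and acute phase genes were also higher, with 4 of 14, 4 of 19, 4 of 19, 2 of 21 and 2 of 12 members called. Over each list alone these counts were 6, 5, 6, 3 and 3, and the camera adjusted p-values were 0.000176, 0.0236, 0.00331, 0.0193 and 0.028. With an estimated correlation the adjusted p-values were 0.203, 0.489, 0.512, 0.512 and 0.334. Their called members included IL1B (1.30), the cell cycle inhibitor CDKN1A (1.42), ADM (1.46), HERPUD1 (1.41) and CFB (0.93).

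All 4 tested metallothioneins, small proteins that bind zinc and copper, fell. MT2A fell by 1.51 from 5404 ± 1060 to 1896 ± 341 TPM, MT1X by 1.89, MT1E by 1.92 and MT1F by 1.04, all close paralogs. Genes of the mitochondrial genome were lower as a list, with 1 of 13 called, also over the list alone (MT-CO3 at -0.89, camera adjusted p = 0.0038, and 0.512 with an estimated correlation). The other large falls were UBBP3 (-3.89), HBA1 (-2.39), STAG2-AS1 (-2.02) and LSP1 (-1.93), of which UBBP3 and HBA1 have near-identical copies and STAG2-AS1 is antisense. A copy of the U2 spliceosomal RNA gene (ENSG00000274432) was listed at 0 in all NC libraries and at 45.9 ± 41.3 TPM in FFA, and is uncertain because U2 has many copies. Of the markers of other cell types, the macrophage-associated genes CD68 (1.61) and CSF1R (0.87) rose, the only 2 leukocyte markers tested. None of 6 stellate cell and 5 cholangiocyte markers was called, and no endothelial marker reached the filter. Of CAR and PXR genes 1 of 4 rose, POR at 0.48.

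The count of 955 was 505 without NC replicate 1, 580 without NC replicate 2, 459 without FFA replicate 1, 427 without FFA replicate 3 and 1474 without FCM replicate 3. With quantile normalization it was 1439, split into 815 higher and 624 lower.

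**Figure D1:**
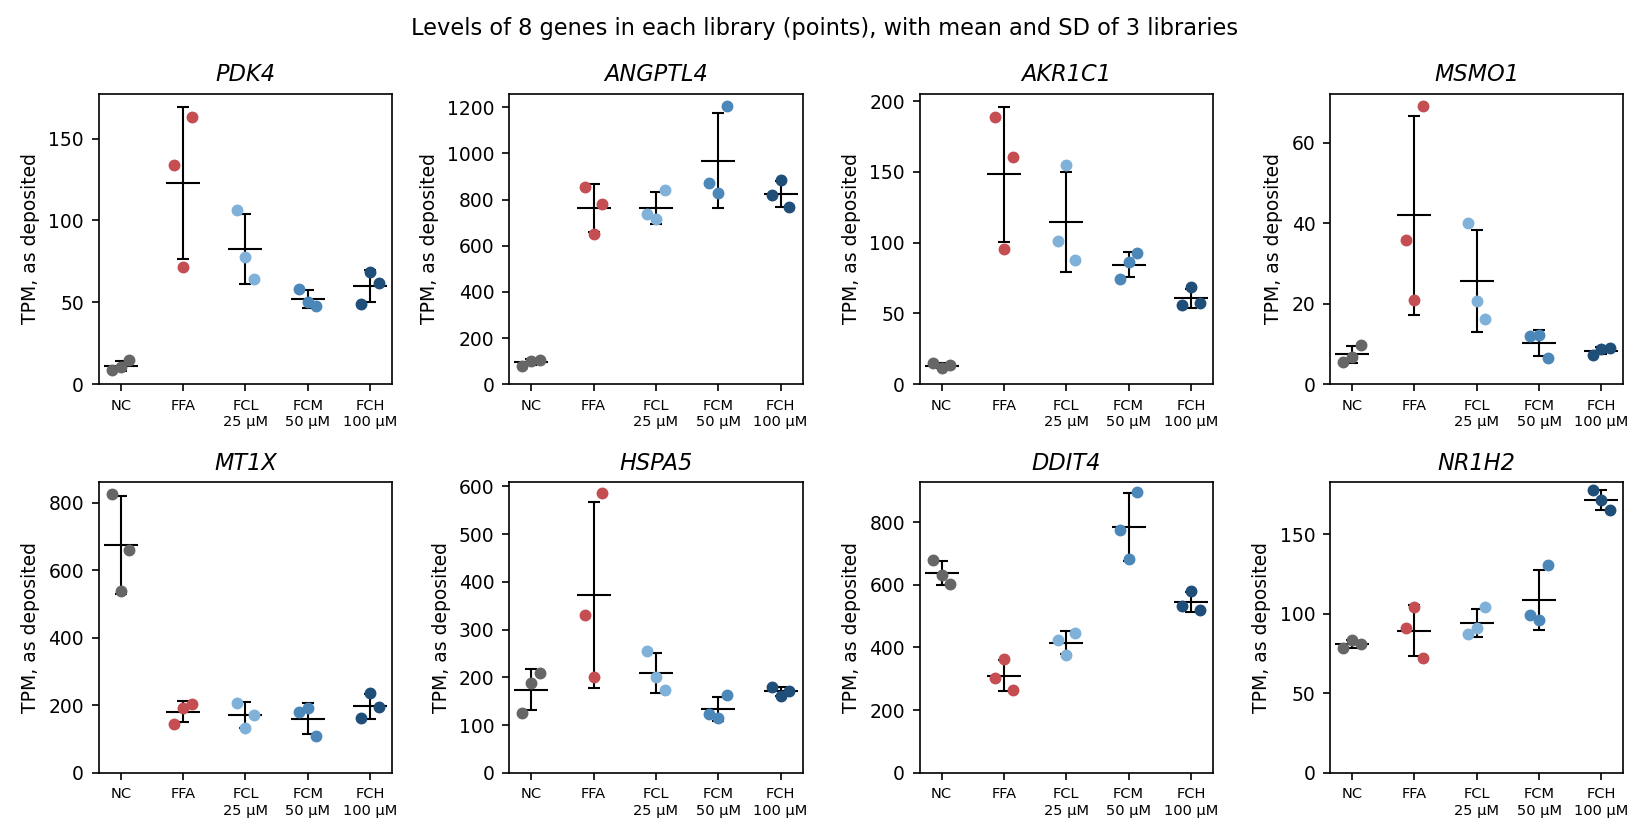
TPM of 8 genes in each library (points), with the mean (dash) and SD (bar) of 3 libraries per group; axes are linear and start at 0. PDK4, ANGPTL4, AKR1C1, MSMO1 and HSPA5 had higher means in FFA than in NC, MT1X and DDIT4 lower ones, and NR1H2 was at 172 ± 6.01 TPM in FCH against 89.2 ± 16.1 in FFA.

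FCL against FFA asks what 25 µM C3R changed under the fatty acids. One gene was called, the U2 copy, listed at 0 in every FCL library as in NC (667 genes had an unadjusted p under 0.05). No lipid gene of the fixed panel was called among the 16 tested. ANGPTL4 was at 763 ± 67.4 TPM against 762 ± 104 in FFA, PDK4 at 82.7 ± 21.5 against 123 ± 46.6, and SCD at 612 ± 161 against 618 ± 85.8. The U2 call was lost without FCM replicate 3 (adjusted p = 0.0603). The count was 0 without NC replicate 1, NC replicate 3, FFA replicate 1, any single FCL replicate or FCM replicate 3, and 2 without FFA replicate 2 or FFA replicate 3.

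As lists, endoplasmic reticulum chaperones (median log2 change -0.21, camera adjusted p = 0.000391), mitosis genes (-0.25, 0.00053) and heat shock genes (-0.20, 0.0167) were lower in FCL than in FFA. The genes of the mitochondrial genome were higher (0.30, 0.000174). No member of these 4 lists was called over all genes or adjusted over the list alone, and every adjusted p was 1 with an estimated correlation.

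FCM against FFA asks the same at 50 µM. In FCM 6 of 25 cholesterol genes, 5 of 21 endoplasmic reticulum chaperones and 6 of 27 mitosis genes fell, and the glucose transporter gene SLC2A1 and DDIT4 rose. The adjusted p of these 3 lists was 0.998 with an estimated correlation. DDIT4 rose from 309.8 ± 49.1 to 784 ± 107 TPM (log2 change 1.34, SE 0.13, adjusted p = 0.000305 by limma), against 637 ± 38.3 in NC. A total of 246 genes were called, 9 higher and 237 lower. The split was 199 higher and 612 lower with median-of-ratios rescaling, and 162 and 359 with quantile normalization. The other large rises were LINC01666 (2.50), SPINK1 (1.51), PGLS-DT (1.07) and WFDC3 (0.99), and SLC2A1 rose by 0.82. PGLS-DT is a divergent transcript next to a coding gene and is uncertain without stated strand use.

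In cholesterol synthesis and uptake 6 of 25 members fell, or 9 adjusted over the list alone (median -0.19, camera adjusted p = 0.0252, and 0.124 with median-of-ratios rescaling). IDI1 fell by 1.85 from 50.5 ± 24.7 to 12.6 ± 3.27 TPM, MSMO1 by 1.82, STARD4 by 1.48 and CYP51A1 by 0.97. Of the endoplasmic reticulum chaperones 5 of 21 fell, or 12 over the list alone (median -0.41, adjusted p = 5.9e-05). They included HSP90B1 (-1.57) and HSPA5 (-1.35), the main chaperones of that compartment. Mitosis genes fell in 6 of 27, or 20 over the list alone (median -0.61, adjusted p = 3.83e-09), among them AURKA (-1.03), TPX2 (-0.93) and CCNA2 (-0.92). Heat shock genes (1 of 14, or 7 over the list alone, HSPD1 at -0.92, adjusted p = 0.0127) and NRF2 targets (2 of 27, or 7, UGDH at -0.98 and TXNRD1 at -0.73, adjusted p = 0.0394) were lower. Glycolysis (1 of 20, also over the list alone, adjusted p = 0.0107) and hypoxia genes (1 of 19, or 2, adjusted p = 0.038) were higher as lists, and in both the called member was SLC2A1. With an estimated correlation the adjusted p was 0.998 for all 7 lists.

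PRR11 (-1.98), HAMP, the iron hormone hepcidin (-1.76), and the U2 copy, listed at 0 in FCM, were the other large falls. PDK4 fell by 1.15 to 52 ± 5.44 TPM, ACSL4 by 1.30, ELOVL5 by 0.88 and CPS1, the entry enzyme of the urea cycle, by 1.19. Of the panel, SCD (-0.51, adjusted p = 0.14), CPT1A (0.03), PLIN2 (0.04) and ANGPTL4 (0.34) did not pass the test. Across genes, which are not independent replicates, deviations from the mean of all libraries correlated with GC content at 0.303 to 0.61 in the 3 FCM libraries and at -0.415 to -0.209 in the 3 FFA libraries (Spearman). All 3 FCH libraries, FCL replicates 1 and 3 and NC replicate 1 also exceeded every FFA library, FCL replicate 3 at 0.411 and FCH replicate 1 at 0.339 the most. Over genes, the log2 change of FCM against FFA correlated with GC content at 0.638 (Spearman). The 237 genes called lower had a median GC content of 42.3%, against 51.2% for all tested genes.

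With a term for the libraries numbered 12 to 15, which include FCM replicate 3, FCM is compared by FCM replicates 1 and 2 alone. Then 33 genes were called, and 7 of 35 named genes stayed called. The median size of the 35 changes was 1.00 (median SE 0.213) before and 1.04 (0.237) with the term. All kept their sign, while some shrank and others grew. This decides nothing on FCM replicate 3 or the batch, because FCM replicates 1 and 2 helped to choose the 35. Of the 7 lists 5 stayed called, and NRF2 targets (adjusted p = 0.135) and glycolysis (0.0913) did not. With the trend over GC content and length removed, 17 genes were called, 4 higher and 13 lower, DDIT4 among them at 1.11 (adjusted p = 0.000703). The count was 1 without FFA replicate 1, 2 without FFA replicate 3 or FCM replicate 2, 62 without FCM replicate 1, 35 without FCM replicate 3, 156, 147 and 63 without FCH replicates 1, 2 and 3 in turn, 160 without NC replicate 2, 600 without NC replicate 1 and 573 without FCL replicate 2.

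FCH against FFA asks the same at 100 µM. A total of 25 genes were called, 14 higher and 11 lower in FCH, and 1946 had an unadjusted p under 0.05. NR1H2, which encodes the oxysterol receptor LXR beta, rose from 89.2 ± 16.1 to 172 ± 6.01 TPM (log2 change 0.95, SE 0.14, adjusted p = 0.0202 by limma). The 3 NC libraries held 78.5 to 83.6 TPM of NR1H2, and FCM replicate 3 held 130.6 TPM. DDIT4 rose by 0.82 to 544 ± 31.4 TPM. MSMO1, a sterol demethylation enzyme, fell by 2.04 from 42 ± 24.6 to 8.39 ± 0.928 TPM, and AKR1C1 by 1.22 to 60.7 ± 6.64 TPM.

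The other large rises were MGC32805 (1.51), SAPCD1 (1.20) and HYPK (0.85). A copy of the signal recognition particle RNA gene (ENSG00000237611) was at 4.56 ± 1.61 TPM in FCH and listed at 0 in all libraries of the other 4 groups. SPARC, a matrix glycoprotein, was at 0.0791 ± 0.102 TPM against 12 ± 5.25 in FFA. It was also at 0.614 TPM in FCM replicate 3, while FCM replicates 1 and 2 held 6.47 and 18.8 TPM, so that the 4 low libraries were those numbered 12 to 15 in the labels. The remaining large falls were the U2 copy (2.96 ± 5.12 TPM), Telomerase-vert (-1.66) and the pseudogene EEF1A1P5 (-1.29), all of which are uncertain because of near-identical copies or short length.

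In cholesterol synthesis and uptake 1 of 25 members fell over all genes, MSMO1, and 11 adjusted over the list alone (median -0.39, camera adjusted p = 6.56e-07). NRF2 targets fell in 1 of 27, AKR1C1, and 11 over the list alone (median -0.32, adjusted p = 8.43e-06). No member of autophagy and lysosome (median -0.23, adjusted p = 4.53e-05), endoplasmic reticulum chaperones (-0.35, 0.000331), mitosis (-0.35, 0.000152) or lipogenesis (-0.25, 0.0131) was called over all genes. Over the list alone 6, 9, 8 and 4 of their members fell, and 1 mitosis gene rose. Immediate early genes were higher (median 0.13, adjusted p = 0.000331, 3 over the list alone), as were genes of the mitochondrial genome (0.15, 0.0402, none over the list alone). With an estimated correlation the adjusted p lay between 0.775 and 0.922 for these 8 lists. Panel genes did not pass the test, including SCD (-0.86, adjusted p = 0.0645), PDK4 (-0.96, 0.116), FGF21 (-0.66, 0.226) and ANGPTL4 (0.12, 0.759).

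All 3 FCH libraries are among those numbered 12 to 15, and with a term for these libraries 4 genes were called. Of the 12 named genes 1 stayed called, the signal recognition particle RNA copy, while the other 11 did not. The term is set by FCM replicate 3 against FCM replicates 1 and 2 alone. With it the log2 changes were smaller in NR1H2 (0.54, adjusted p = 0.176), DDIT4 (0.52, 0.172), EEF1A1P5 (-0.78, 0.216) and MSMO1 (adjusted p = 0.302), and most of all in SPARC (-0.61, 0.581). They kept about their size or grew in MGC32805 (1.53), SAPCD1 (1.13), HYPK (0.81), AKR1C1 (-1.42), Telomerase-vert (-2.18) and the U2 copy, while the median SE of the 12 rose from 0.217 to 0.393. Of the 8 lists 5 stayed called, and NRF2 targets (adjusted p = 0.428), mitosis (0.0521) and immediate early genes (0.917) did not. With the batch adjustment of FCH replicate 3 undone, MSMO1 (adjusted p = 0.085) and Telomerase-vert (0.109) were no longer called, while NR1H2 (0.92, 0.0281), DDIT4 (0.78, 0.0281) and AKR1C1 (-1.25, 0.0499) were, and AKR1C1 was not called with the trend over GC content and length removed (0.0538). The count was 1 without FCH replicate 2, 2 without FCH replicate 1, FCH replicate 3 or FFA replicate 3, 3 without FFA replicate 1, 78 without FFA replicate 2, 86 without FCL replicate 2 and 190 without FCM replicate 3.

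**Figure D2:**
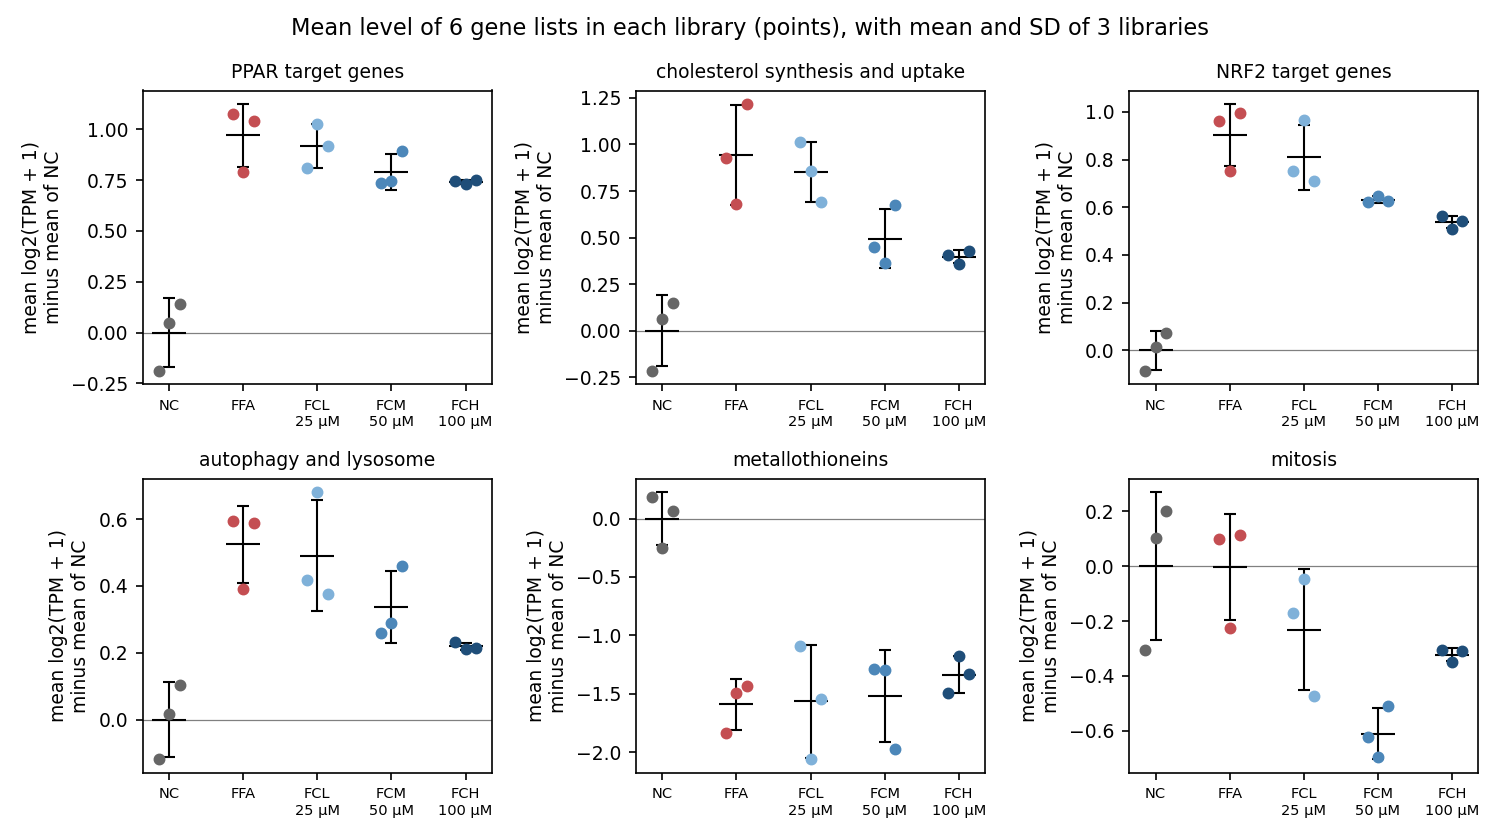
Mean of log2(TPM + 1) over the tested members of 6 gene lists in each library (points), minus the mean of NC, with the mean (dash) and SD (bar) of 3 libraries per group. Cholesterol genes stood at 0.94 in FFA, 0.85 in FCL, 0.50 in FCM and 0.40 in FCH, and metallothioneins between -1.59 and -1.33 in all 4 groups with fatty acids.

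FCH against FCL and the dose trend ask whether C3R acted by dose. FCH and FCL differed in 10 genes, 5 higher and 5 lower in FCH. They included NR1H2 (0.86, SE 0.14, adjusted p = 0.0363 by limma), PTMS (0.77) and the long noncoding RNA LINC00958 (-0.82), the last pair named after their values were seen. The dose trend over 12 libraries called 48 genes, 21 rising and 27 falling. Rising genes included NR1H2 (0.98 per 100 µM, adjusted p = 0.0335) and HYPK (0.88), and falling ones included MSMO1 (-2.09), AKR1C1 (-1.22), SQLE (-1.09), SCD (-0.93, adjusted p = 0.0418) and the lysosomal lipase LIPA (-0.92), which is named after its values were seen. The dose trend split was 35 rising and 8 falling with median-of-ratios rescaling, 52 and 30 with quantile normalization and 13 and 5 without the mitochondrial genes. FCH against FCL gave 42 higher and 14 lower with the first scaling and 33 and 21 with the second, and FCH against FFA 20 and 10 without the mitochondrial genes. With the trend over GC content and length removed, FCH against FFA gave 21 higher and 38 lower and FCH against FCL 24 and 40, and the stricter filter gave 19 and 40 for FCH against FFA. A fit on FCH and FFA alone gave 197 higher and 543 lower, array weights 956 and 2441, and a pseudocount of 0.1 gave 17 and 25.

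With the term for libraries 12 to 15 the dose trend called 0 genes and FCH against FCL 571, 108 higher and 463 lower. In FCH against FCL the term is set by FCM replicate 3 against FCM replicates 1 and 2 alone. It moved the median log2 change of all genes from -0.054 to -0.242, so the 571 do not show a larger dose difference. With the adjustment undone, 2 genes were called for FCH against FCL and 6 by the dose trend, NR1H2 among the latter (0.95, adjusted p = 0.044). Without FCH replicate 1 or FCH replicate 3 both called 0 genes. FCH against FCL called 1 without FCH replicate 2, 2 or 3 without NC replicate 1, NC replicate 3, any single FFA replicate, FCL replicate 2, FCL replicate 3 or FCM replicate 1, 23 without FCL replicate 1 and 114 without FCM replicate 3. The dose trend called 1 without FFA replicate 1 or FCH replicate 2, 2 without FCL replicate 3, 3 without FFA replicate 3, 6 without FCL replicate 1, 16 without FCM replicate 1, 73 without FFA replicate 2, 107 without FCL replicate 2 and 161 without FCM replicate 3.

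The covariance across genes of the fatty acid change (FFA minus NC) and the C3R change (C3R group minus FFA) asks whether C3R ran against the fatty acids. In FCH it was -0.0599, against -0.0391 simulated for unchanged groups that share the FFA libraries. The difference was -0.0208 (SD 0.00323 over the 3 FCH libraries, 3 of 3 below 0), a slope of -21.4% of the fatty acid change. In FCM the difference was -0.00562 (SD 0.0173, 2 of 3 below 0) and in FCL 0.00738 (SD 0.00822, none below 0), both within this spread. Within a group the 3 values share the FFA and NC means, so these SDs leave out the spread of the FFA and NC libraries. The batch adjustment can also make the SD of FCH too small. Correlations were -0.364, -0.285 and -0.278 in FCH, FCM and FCL, against -0.499 simulated. Of all genes 66.2% had the opposite sign in FCH, 60.3% in FCM and 56.5% in FCL, against 66.7%, 66.6% and 66.6% simulated for unchanged groups. The simulated groups held no fatty acid change, and a real one weakens both the correlation and this share. Neither measure can therefore decide whether C3R ran against the fatty acids. Of the 955 genes called for FFA against NC, 83.8%, 72.7% and 62.9% had the opposite sign in FCH, FCM and FCL. The shared FFA libraries helped to choose these genes, which favors opposite signs. The FCH difference was -0.0436 without FFA replicate 2 and 0.0006 without FFA replicate 3.

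The changes of the 3 C3R groups from FFA were also compared with each other. The covariance of FCM and FCH exceeded that simulated with shared FFA libraries by 0.0517, that of FCL and FCM by 0.0256 and that of FCL and FCH by 0.00242. Correlations were 0.615, 0.629 and 0.386, against 0.498, 0.497 and 0.495 simulated. FCM replicate 3 correlated at 0.981 with FCH replicate 1 and at most at 0.971 with the other FCM libraries. Without it, an alternative chosen after the values were seen, the excess was 0.0194 for FCM and FCH and 0.0148 for FCL and FCM. The correlations were then 0.414 and 0.55, against 0.451 and 0.449 simulated. The simulated groups held no change, and a change in 1 group alone lowers a correlation. The correlations therefore do not decide whether changes were shared.

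Against NC, the C3R groups kept much of the fatty acid change. FABP3 was at 86.3 ± 24.4 TPM in FCL, 107 ± 57 in FCM and 83.6 ± 28.2 in FCH, against 2.62 ± 0.653 in NC. FCL differed from NC in 1175 genes (843 higher, 332 lower), FCM in 1689 (821 and 868) and FCH in 648 (391 and 257). Quantile normalization gave 992 higher and 700 lower for FCL and 1281 and 1110 for FCM, and median-of-ratios rescaling 1607 and 1228 for FCM. Array weights gave 2421 and 2359 for FCL, 1873 and 3989 for FCM and 2162 and 2953 for FCH. Without NC replicate 1, FCM gave 512 higher and 1294 lower and FCH 222 and 250. With the term for libraries 12 to 15 the counts were 1954, 993 and 54 for FCL, FCM and FCH. The counts moved by over 1.5 times without single libraries. FCL against NC gave 675, 703 and 689 without NC replicates 1, 2 and 3 in turn, 772 without FCL replicate 3 and 1960 without FCM replicate 3. FCM against NC gave 906 without NC replicate 2, 724 without NC replicate 3 and 1005 without FCM replicate 3. FCH against NC gave 355 without NC replicate 2, 344 without NC replicate 3, 289, 293 and 313 without FCH replicates 1, 2 and 3 in turn, and 1233 without FCM replicate 3. Of the genes higher in FFA, 558 were also higher in FCL, 468 in FCM and 282 in FCH, where independent lists would share 46.1, 44.9 and 21.4, and none went the opposite way in either direction. The covariance of these changes with that of FFA was 0.144, 0.131 and 0.115, against 0.0386, 0.0397 and 0.0396 simulated, and part of each overlap may come from the shared NC libraries.

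**Figure D3:**
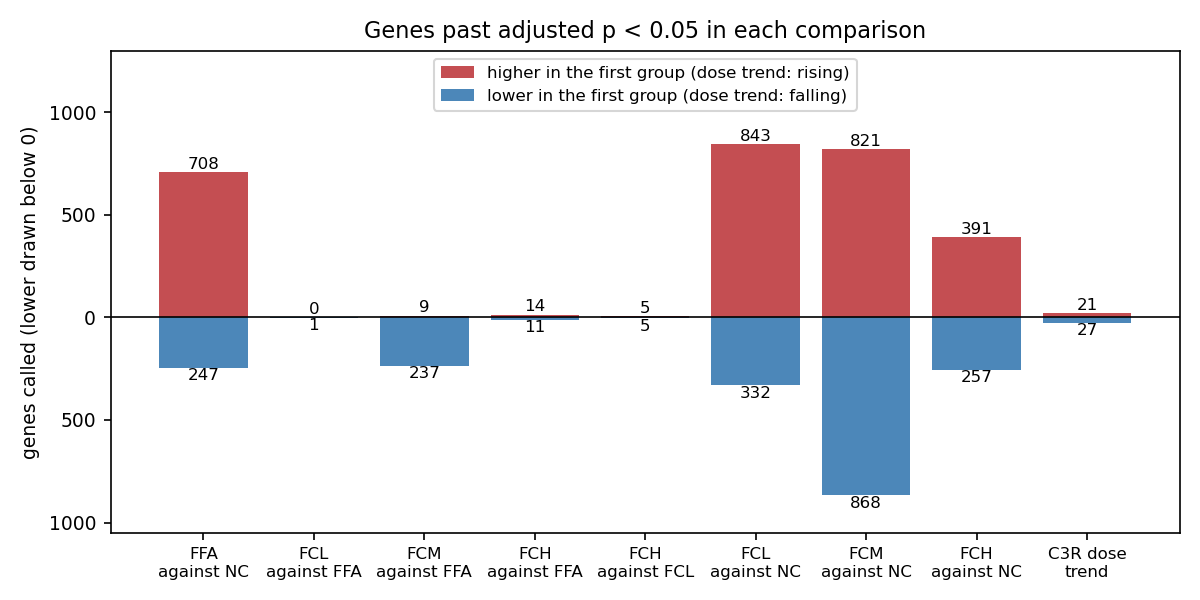
Number of genes called at an adjusted p under 0.05 in each comparison, those higher in the group named first (or rising with dose) above 0 and those lower below it. FFA against NC gave 955 genes and the 3 C3R groups against FFA 1, 246 and 25.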

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

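The tests of the GC content trend, of brain RNA, of C3R dose and library batch as sources of the neural transcripts, of the mitosis list in FCM replicates 1 and 2, of the calls without FCM replicate 3, of the batch adjustment and of dose draws with it undone were chosen only after the results were seen. The others were chosen before.

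Differences between the C3R doses were tested directly. FCH and FCL differed in 10 genes, among them NR1H2 (log2 difference 0.86, adjusted p = 0.0363, and 0.83 with 0.0507 once the batch adjustment of FCH replicate 3 was undone, so the change stayed about as large and the adjusted p passed 0.05) and a signal recognition particle RNA copy, Metazoa_SRP ENSG00000237611, with a difference of 2.44 on the log2(TPM + 1) scale because FCL is listed at 0. FCM and FCL differed in 1 gene, DDIT4 (0.91, adjusted p = 0.0401, and 0.91 with 0.0641 once the adjustment was undone), chosen for naming after its value was seen. Neither group holds the adjusted library, but all 15 libraries share 1 estimate of the spread, so the adjustment reaches these p-values too. With it undone, FFA against NC called 862 genes in place of 955, and FCM against FFA 172 in place of 246. FCH and FCM differed in 2 genes, ADAM10 (1.27, adjusted p = 0.0216), also named after its value was seen, and Metazoa_SRP ENSG00000237611 (2.44).

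Most genes called for FCM against FFA were lower in FCM, 237 of 246. For the mitosis list FCM replicate 3 alone was argued against, since FCM replicates 1 and 2 lay below FFA by a mean log2 difference of -0.656 (SD of FFA 0.193, of NC 0.269). This bears on FCM replicate 3 alone and not on the GC trend, which all 3 FCM libraries shared. For the 237 genes FCM replicate 3 alone stays open. Genes picked as lowest in it had medians of -0.334, -0.166 and -0.175 in FCM replicates 1 and 2, against -0.138, -0.175 and -0.17 for random gene sets (SD 0.027, 0.028 and 0.022). Without FCM replicate 3, 35 genes were called, 32 of them lower and 30 among the 237. FFA replicates 1 and 3 set against FFA replicate 2 and FCM replicates 1 and 2 gave 29. That grouping differs from the real one only in the side of FFA replicate 2, so it keeps much of the real contrast and decides little. The remaining choices of 2 of these libraries called at most 1 gene. The median of the 237, -0.932 (SD 0.376) without FCM replicate 3, decides nothing because FCM replicates 1 and 2 helped to choose them. With each library's trend over GC content and length removed, 17 genes were called and 12 of the 237 stayed called, as their median log2 change went from -0.927 (SD 0.361) to -0.631 (SD 0.382). The GC trend and C3R cannot be told apart for the 237 genes, because all 3 FCM libraries correlated more with GC content than all 3 FFA libraries, as did all 3 FCH libraries, FCL replicates 1 and 3 and NC replicate 1.

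Of 20 listed transcripts typical of neural tissue, 17 were above 0.1 TPM in each of 11 libraries and far below their median there in FCM replicate 3 and the 3 FCH libraries, where the highest of the 20 reached 2.56 TPM. Human brain tissue was argued against: 19 other abundant brain genes differed by a median of 0.03 TPM, against 1.66 TPM for the 20 neural transcripts, and 4 of the 19 reached 1 TPM. Some of the 19 did go with the pattern, such as SLC1A2 (median 0.31 TPM in the 11 libraries, at most 0.01 in the 4) and VSNL1 (0.573, at most 0.193). Others did not, such as NRGN (4.02, up to 6.08) and OLFM1 (5.33, up to 7.37), and AQP4, MOG and CCK were at 0 in every library. C3R dose was argued against, since the 20 transcripts had a median of 0.00144 TPM in FCM replicate 3 and 2.38 TPM in FCM replicates 1 and 2. A library batch may be the source: these are the 4 last library numbers, and 58 genes had the pattern, against at most 4 for any other of the 1365 subsets of 4 libraries. This batch includes all of FCH, so the FCH results and the batch are confounded, and RNA of another species was not tested.

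The batch adjustment of FCH replicate 3 was weighed for the genes called with FCH. For FCH against FFA it was argued against as the whole cause, since 19 genes were called with it undone and all 19 were among the 25. For FCH against FCL, 2 genes in place of 10 were called with it undone, and for the dose trend 6 in place of 48. The log2 changes moved little, from a median size of 1.80 (median SE 0.226) to 1.86 (0.237) in the 10 genes and from 0.90 (0.162) to 0.86 (0.164) in the 48, and each kept its sign. The calls ended as adjusted p-values passed the threshold, up to 0.0954 and 0.214, so whether the adjustment made these calls stays open, as does C3R.

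Other splits of the same 6 libraries were counted for each comparison, and 10 splits are too few for a share under 0.05. In another split, a real group difference adds to the spread within groups and lowers the count. The gap between the real and the other counts of genes is therefore no measure of calls made by chance. FFA against NC called 955 genes and 18 lists, and the highest other split 1 gene and 16 lists (1 of 10 splits as large in both). FCL against FFA called 1 gene and 4 lists, and other splits up to 2 genes and 10 lists (5 and 6 splits as large). FCM against FFA called 246 genes and 7 lists, and other splits up to 4 genes and 8 lists (1 and 4 splits). FCH against FFA called 25 genes and 8 lists, and other splits up to 0 genes and 10 lists (1 and 3 splits). FCH against FCL called 10 genes against 1, FCM against NC 1689 against 5, and FCH against NC 648 against 3 (1 split each). FCL against NC called 1175 against 439 (1 split), the latter with NC replicate 1, FCL replicate 1 and FCL replicate 3 on one side, which points to a structure of the samples beyond the groups. These libraries correlated with GC content at -0.029, 0.065 and 0.411. On the other side, NC replicates 2 and 3 and FCL replicate 2 did so at -0.279, -0.512 and -0.266. Whether the GC trend made the 439 calls was not tested. For the dose trend 1 of 100 draws of the doses, the real one, gave 48 genes, and the highest other 10, but the adjustment narrows the spread of FCH in the real arrangement. With it undone, 2 of 100 draws gave as many as the real 6 genes, and the highest other gave 11. The trend called 0 genes without FCH replicate 1 or FCH replicate 3 and 1 without FCH replicate 2, so its calls needed all 3 FCH libraries. The adjusted p-values of the 48 by limma lay between 0.0157 and 0.0486. Fewer libraries could thus end the calls without smaller slopes, and no single library is shown to carry the trend.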

How the results depend on the processing

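Undoing the batch adjustment (alone or with array weights), removing the GC and length trend and a library batch term were chosen after seeing the data. Named genes called in a comparison gave 4121 values under alternatives: 3397 stayed called, 724 did not, and 0 reversed. Most values were of FFA against NC, with 95 called named genes, against 1, 35 and 12 for FCL, FCM and FCH against FFA. Calls of the C3R groups were lost in a larger share of the alternatives. A replicate block kept 89 of 95 for FFA against NC, 14 of 35 for FCM and 8 of 12 for FCH. Median-of-ratios rescaling kept 88 of 95, 35 of 35 and 11 of 12. Other alternatives kept far fewer of the C3R calls. No filter kept 76 of 95, 2 of 35 and 3 of 12. Fits on the compared groups alone kept 86 of 95, 0 of 35 and 11 of 12. Without FFA replicate 1, 72 of 95, 1 of 35 and 2 of 12 were kept. Without FCH replicate 1 or FCH replicate 2, FCH against FFA kept 0 of the 11 named genes still tested. The 54 panel values not called gave 1553 values, of which 57 were called in the same direction and 0 in the opposite one. The depth is unknown, so its effect could not be measured. Unless stated, the cause was not tested.

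A pseudocount of 0.1 gave 0 genes for FCL against FFA, 42 for FCH against FFA (17 higher, 25 lower) and an FCH opposition difference of -0.0338. No filter gave 11 for FCM against FFA, 12 for FCH against FFA (11 higher, 1 lower), 5 for FCH against FCL, 955 for FCM against NC, 0 for the dose trend and an FCH opposition of -0.0101. A stricter filter gave 59 for FCH against FFA, 5 for FCH against FCL and 87 for the dose trend. Median-of-ratios rescaling gave 811 for FCM against FFA, 72 for FCH against FFA, 56 for FCH against FCL, 2835 for FCM against NC, 1065 for FCH against NC, and 4 lists for FCM against FFA. Quantile normalization gave 1439 for FFA against NC, 0 for FCL against FFA, 521 for FCM against FFA, 96 for FCH against FFA, 54 for FCH against FCL, 1247 for FCH against NC and 82 for the dose trend. Leaving out the mitochondrial genes gave 18 for the dose trend.

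Array weights gave 2574 for FFA against NC, 873, 3964 and 3397 for FCL, FCM and FCH against FFA (the last 956 higher and 2441 lower), 5067 for FCH against FCL, 4780, 5862 and 5115 for FCL, FCM and FCH against NC, and 2804 for the dose trend. With the adjustment also undone these were 2370, 647, 1913, 917, 1582, 4584, 3918, 2376 and 551. The weight of FCH replicate 3 was 100.5 as deposited and 1.64 with the adjustment undone. Undoing the adjustment alone gave 2 for FCH against FCL and 6 for the dose trend. Removing the GC and length trend gave 17 for FCM against FFA, 59 for FCH against FFA and 64 for FCH against FCL. A library batch term gave 1463 for FFA against NC, 0, 33 and 4 for FCL, FCM and FCH against FFA, 571 for FCH against FCL, 1954, 993 and 54 for FCL, FCM and FCH against NC, and 0 for the dose trend.

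A replicate block gave 66 for FCM against FFA, 16 for FCH against FFA, 2 for FCH against FCL and 3 for the dose trend. Replicate numbers did not pair the samples, with correlations over genes between -0.171 and 0.154. Fits on the groups of the comparison alone gave 0, 1 and 740 for FCL, FCM and FCH against FFA (the last 197 higher and 543 lower), 29 for FCH against FCL, and 455, 454 and 1601 for FCL, FCM and FCH against NC. By construction a fold minimum lowered the counts, to 258 for FFA against NC, 96 and 14 for FCM and FCH against FFA, 6 for FCH against FCL, 262, 367 and 210 for FCL, FCM and FCH against NC, and 20 for the dose trend. The estimated correlation left 1 list for FFA against NC and 0 for FCL, FCM and FCH against FFA. Cross-fitting gave an FCH opposition of -0.0278. The dose as a rank gave 1 gene, and the dose trend without the FFA group 5.

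Called lists kept their direction under the scalings. Calls lost were p53 targets for FFA against NC with median-of-ratios rescaling (adjusted p = 0.0581) and quantile normalization (0.067), and mitochondrial genes with the latter (0.128). For FCM against FFA, cholesterol (0.124), NRF2 (0.214) and hypoxia (0.121) were lost with the first, glycolysis (0.174) and hypoxia (0.186) with the second. For FCH against FFA, mitochondrial genes were lost with both (0.121 and 0.32). With the library batch term, 2 of 7 list calls were lost for FCM against FFA and 3 of 8 for FCH against FFA. No filter lost 1 each of 18, 7 and 8 for FFA against NC, FCM against FFA and FCH against FFA, the stricter filter 4 of 16 and 1 of 7 for the first pair, and the GC and length trend removed 1 of 7 for FCM against FFA. For FFA against NC, calls lost were 2, 1 and 2 without NC replicates 1, 2 and 3 and 3 without FFA replicate 3. For FCL against FFA they were 1 of 4 without FFA replicate 1 and 2 without FFA replicate 3 or FCL replicate 3. For FCM against FFA they were 1 without FCL replicate 1 or FCM replicate 1, 2 without FFA replicate 2, FFA replicate 3 or FCM replicate 3, and 3 without FCM replicate 2. For FCH against FFA they were 1 without FFA replicate 3 or FCH replicate 3 and 2 without FCH replicate 2. None reversed.

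Leaving out each library in turn gave 427 to 1474 for FFA against NC, 0 to 2, 1 to 600 and 1 to 190 for FCL, FCM and FCH against FFA, 0 to 114 for FCH against FCL, 675 to 1960, 724 to 2119 and 289 to 1233 for FCL, FCM and FCH against NC, and 0 to 161 for the dose trend. Lists called numbered 17 to 20 for FFA against NC and 2 to 7, 4 to 8 and 6 to 9 for FCL, FCM and FCH against FFA. The opposition difference ranged from -0.00861 to 0.0258 in FCL, -0.027 to 0.0141 in FCM and -0.0436 to 0.0006 in FCH, reversed without FFA replicate 3. Without FCM replicate 3 the covariance excess of FCM and FCH was 0.0194 in place of 0.0517 and that of FCL and FCM 0.0148 in place of 0.0256. Where a group kept 2 libraries, the pooled spread of all groups was used.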

Other observations

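Other gene groups fixed in advance moved little or in mixed directions with the fatty acids. Among antioxidant enzymes 3 of 20 rose (5 adjusted over the list alone), SOD2 at 1.29, CAT at 1.01 and GPX1 at 0.74, and SOD1 fell by 0.35. Of interferon genes 1 of 13 rose, OAS1 at 1.19, and 2 fell, IFITM3 by 0.68 and ISG15 by 0.62 (1 and 3 over the list alone). DNA replication genes rose in 2 of 26, E2F1 at 0.85 and CDT1 at 0.72, or 5 over the list alone, while none of 27 mitosis genes was called by limma. The camera tests of these lists had adjusted p-values of 0.105, 0.235, 0.0814 and 0.421. LXR targets, named for the receptor family of NR1H2, had 2 of 7 members higher in FFA, or 3 higher and 3 lower over the list alone (camera adjusted p = 0.942). In FCH against FFA, where NR1H2 was called higher, none of the 7 was called, and 1 fell over the list alone. There 2 members had a higher mean and 5 a lower one (median log2 change -0.088, camera adjusted p = 0.448).

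A hypothesis was that 4 of the 6 lists lower in FCH than in FFA fall with the C3R dose over the 9 libraries given C3R. These 4 tests were chosen before their results were seen, and tests of the other 2 lists after, but the lists were chosen because they were lower in FCH, so they are not independent of it. Two-sided exact permutation tests over 1680 arrangements, adjusted over 4 lists, gave slopes per 100 µM of -0.549 for cholesterol synthesis and uptake (p = 0.0185, adjusted 0.0247), -0.337 for NRF2 targets (p = 0.00357, adjusted 0.0143), -0.344 for autophagy and lysosome (p = 0.0179, adjusted 0.0247) and -0.244 for lipogenesis (adjusted 0.211). The other 2 lists had slopes near 0, -0.022 for mitosis and -0.059 for endoplasmic reticulum chaperones, with exact permutation p-values adjusted over 6 lists of 0.93 and 0.845. Adjusted over 6 lists, the first 3 had p-values of 0.037, 0.0214 and 0.037. With the adjustment of FCH replicate 3 undone the first 4 slopes were -0.501, -0.318, -0.34 and -0.189. Their exact permutation p-values were then 0.0357, 0.00476, 0.0208 and 0.352, not adjusted over the lists. Those of mitosis and endoplasmic reticulum chaperones were 0.987 and 0.798. With Benjamini-Hochberg over these 6 lists and the batch adjustment undone, NRF2 targets stay under 0.05. Cholesterol synthesis and uptake and autophagy and lysosome then do not. The mean of all genes had a slope of -0.026 (exact permutation p = 0.826). A graded fall may hold for NRF2 targets and not for all lists lower in FCH. For cholesterol synthesis and uptake and for autophagy and lysosome it passed 0.05 over 6 lists only with the deposited values. The dose also runs with the batch of the 4 last libraries.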
